A study of Mus musculus with 115 samples.

How the data were processed

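Ovarian cells of wild type, db/db and ob/ob mice were collected by hand under a stereomicroscope after collagenase treatment, lysed singly and tagged with 1 of 96 cell barcodes, per the labels' protocols. Each library pooled up to 96 barcoded cells and was sequenced on an Illumina HiSeq X-Ten instrument. The authors deposited 1 table of raw UMI counts per gene and cell, in which every value used was a whole number. The submitters' processing notes name the mm9 genome build. The aligner, the counting tool and the annotation are not given in the sources used here. The table held 24579 rows, of which 92 were ERCC spike-in molecules and 3 were RGC rows. Both kinds were left out of totals and tests, and the ERCC molecules took 22.4% of the UMIs of the cells kept.

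Of 13254 cell columns, 10000 belonged to 115 libraries that the labels describe. The other 3254 columns, of 38 libraries, were not used. The series text names diets, but no label used here gives one, so diet was not compared. Groups followed the genotype and cell type labels: 31 wild type, 30 db/db and 31 ob/ob libraries of somatic cells, 12 wild type, 4 db/db and 4 ob/ob libraries of oocytes, 2 db/db libraries described as holding both, and 1 library with no genotype. The last 3 libraries entered no comparison. Replicate numbers were given in accession order and only name a library. No pair of kept cells had identical counts, so no library entered as an exact copy of another.

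Cells with at least 1000 genes and 3000 UMIs were kept, which left 9268 cells. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.5 (scanpy 1.11.5, igraph 0.11.9) gave 26 clusters. A cluster was called oocyte-like, granulosa-like and so on where 1 of 12 marker lists led the next by a relative level of 0.15, at least 3 of its markers were detected in 25% of cells, fewer than 3 markers of another class that its own list lacks stood among its 50 leading genes, RNA without poly(A) or histone genes did not lead it and no 2 libraries held over 80% of it. The marker lists, the cell filter, the comparisons, the tests, the pathway lists and the rule for named genes were fixed before the data were examined. The resolution and the naming margins were set after several clusterings had been looked at and before any genotypes were compared. No doublet caller was run, since each well received 1 hand-picked cell.

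Cells are not replicates. UMI counts of the cells of 1 class were summed per library, a library entered with at least 5 such cells, and another somatic class was tested where at least 3 libraries in each of 2 genotypes or more met that minimum. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood tests (R 4.3.3) in 1 fit of the 3 genotypes, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. Every adjusted p of a gene given in the text comes from that test unless another tool is named. CPM values follow TMM scaling and are given as mean and SD over libraries. The 27 pathway lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the estimated correlation. For each comparison the named genes are the 8 largest rises and the 8 largest falls among passing genes with a mean of at least 20 CPM, up to 4 members of each passing list with the smallest adjusted p, and Lep, Lepr, Nnt and Ifi202b. Predicted and ribosomal protein genes are counted but mostly not named. Not every gene the rule gives is printed.

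The labels name no animal, so the libraries are the replicates and p-values measure only the spread between libraries, which may be technical. Wild type libraries carry the strain label C57BL/6-129Sv and numbers 1 to 59, whereas the mutant libraries carry C57BL/6 and numbers from 82 to 153. Genotype against wild type is therefore confounded with strain and with the order of libraries. The db/db and ob/ob libraries share a strain label and came in alternating blocks of numbers.

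Simulated counts with 200 changed genes, drawn from the fitted means, dispersions and depths of the real libraries, were put through the same test. In the granulosa-like class the test recovered 71% of genes changed by a log2 of 1 and 99% of those changed by a log2 of 2 for db/db against wild type. In oocytes the same comparison recovered 2% and 44%, in luteal-like cells 26% and 83%, and in stroma-like cells 2% and 24%. For db/db against ob/ob it recovered 0% and 8% in oocytes and 3% and 18% in stroma-like cells.

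Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma 3.58.1 on the mean CPM of cells with a pseudocount of 1, no low count filter, a stricter cell filter of 2000 genes and 10000 UMIs, at least 10 cells per library, only the genotypes compared, only the largest cluster, the mixed libraries added, the library number as a covariate and, for genotypes with 2 to 5 libraries in a comparison, each library of that genotype left out in turn. Other clustering resolutions, mitochondrial rows left out, single clusters, added unnamed clusters, library number subsets and 7 doubted libraries left out were chosen after seeing the data. The doubted libraries were wild type somatic replicates 27 and 28, db/db replicates 9, 18 and 23 and ob/ob replicates 5 and 21. Spike-in shares were 0.198% and 0.352% in wild type replicates 27 and 28. Some others were doubted for oocyte transcripts. Replicate 5 of ob/ob held 1 granulosa-like cell, so it was not in the granulosa-like fit. Groups of libraries were also split anew, with 50 draws for granulosa-like cells and 100, or all 35 that exist, for other classes. The similarity of both mutants' effects was compared with simulated unchanged groups and with the wild type libraries split between the comparisons. The 37 mitochondrial rows carry transcript identifiers that were matched to names in GENCODE vM21 (GRCm38), which served for names, chromosomes and the order of genes only.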

Results

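Single-cell RNA was counted in libraries of hand-picked mouse ovary cells from wild type, db/db and ob/ob animals. The db allele alters the leptin receptor gene Lepr and the ob allele the leptin gene Lep, and both genotypes become obese. The title of the series sets the question, which is how obesity changes the cells of the growing follicle. After filtering, 9268 cells remained. UMI totals per somatic library ran from 2017017 to 22488226 in wild type, from 2778201 to 19202518 in db/db and from 4793175 to 16581125 in ob/ob. Oocyte libraries held 2070988 to 17827995 UMIs in wild type, 4365254 to 19719043 in db/db and 4488036 to 21249964 in ob/ob. Genotype against wild type is confounded with strain and with the order of libraries. The db/db and ob/ob libraries share a strain label and came in alternating blocks, which were not balanced in luteal-like cells.

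Clustering gave 26 clusters. Granulosa-like cells, the somatic cells that surround the oocyte, filled clusters 1, 3, 5, 7, 18 and 22. Clusters 1, 18 and 22 had no granulosa marker among their 50 leading genes. Cluster 1, the largest of the class, had a relative level of 0.347, with 10 of 15 markers detected. Its cells had a median of 2025 genes and 5.14% mitochondrial UMIs, so its name is less certain. Luteal-like cells filled clusters 4 and 10, stroma-like cells cluster 2, theca-like cells cluster 17, surface epithelium-like cells cluster 16 and oocyte-like cells clusters 8, 11 and 15. Granulosa-like cells were spread differently over the clusters. Cluster 1 held 332 wild type, 341 db/db and 216 ob/ob cells, cluster 3 held 455, 100 and 1.3e+02, cluster 5 held 71, 367 and 214, and cluster 7 held 129, 287 and 173. Granulosa-like cells made up a median of 46.3% of the cells of a wild type somatic library, 52.1% in db/db and 29.8% in ob/ob. Stroma-like cells made up a median of 29.2%, 1.98% and 2.74%. Clusters in which granulosa markers led but which the naming rule left unnamed held 9.52% of all wild type somatic cells, 20.2% of db/db and 20.7% of ob/ob. Picking cells by hand can set these shares, and they were not tested. Theca-like cells reached the minimum in 13 wild type, 0 db/db and 2 ob/ob libraries and surface epithelium-like cells in 0, 0 and 8, so neither class was compared.

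The targeted genes were read first. Lep, the leptin gene, had 0 UMIs in the 31 wild type somatic libraries, 1 UMI in the 30 db/db ones and 3 in the 31 ob/ob ones, and 5, 3 and 4 UMIs in the oocyte libraries. Lepr, the leptin receptor gene, was present in oocytes at 12.97 ± 8.84 CPM in wild type (SD, n = 12), 5.87 ± 2.36 in db/db (n = 4) and 19.8 ± 9.58 in ob/ob (n = 4). Neither mutant differed from wild type in Lepr over the oocyte class, with edgeR adjusted p = 0.380 for db/db and 0.834 for ob/ob. That depended on the clusters, since within cluster 8 alone Lepr fell in db/db to 7.70 ± 4.84 CPM from 28.7 ± 11 in wild type (adjusted p = 0.00171). Over whole somatic libraries Lepr stood at 2.70 ± 4.19 CPM in wild type (n = 31), 3.45 ± 7.27 in db/db (n = 30) and 2.24 ± 3.48 in ob/ob (n = 31). Counts per gene do not separate transcript forms, so they do not check the genotype labels. Of the strain markers, Ifi202b stood at 27.2 ± 34.8 CPM in wild type somatic libraries, 0.883 ± 2.63 in db/db and 0.880 ± 3.38 in ob/ob, and Nnt at 29.7 ± 17.5, 26.9 ± 14.7 and 24.1 ± 16.03.

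**Figure D1:**
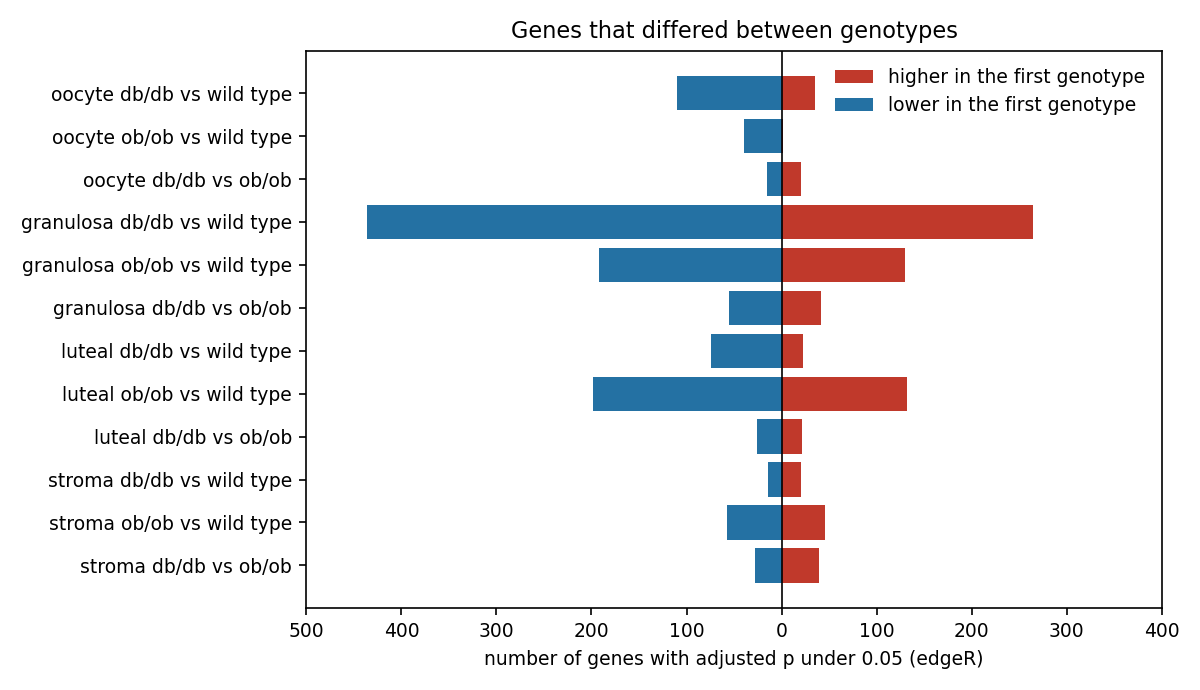
Number of genes past an adjusted p of 0.05 in each comparison (edgeR). Bars to the right count genes higher in the first genotype named and bars to the left genes lower in it; granulosa-like cells of db/db against wild type had 265 and 436.

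In db/db oocytes 35 genes rose and 110 fell against wild type. Acsl5, which activates long-chain fatty acids, rose from 0.380 ± 0.513 CPM (n = 12) to 126.3 ± 57.2 (n = 4), a log2 change of 8.42 (adjusted p = 2.91e-07). H2-Aa, a class II histocompatibility chain, rose by a log2 of 5.43, Pigp, of glycosylphosphatidylinositol anchor synthesis, by 3.40, Trim15 by 3.35, the lysosomal mannosidase gene Manba by 2.70 and Anxa2 by 2.35. The mitochondrial gene mt-Nd3 fell from 1011 ± 986 CPM to 0.0486 ± 0.0709. The same row was also far below wild type in db/db granulosa-like, luteal-like and stroma-like cells, so the fall is not particular to oocytes. Whether less RNA was made or reads were assigned to this row differently was not tested. Slc27a2, a fatty acid transporter gene, fell by 7.14 on the log2 scale, AA465934 fell by 7.18, Gsto2 fell by 6.38, the adhesion gene Epcam fell by 5.73, Mtfr2 fell by 5.60 and Sspn fell by 5.50. As a list, oxidative phosphorylation genes lay higher in db/db, with 42 of 50 members positive and none past the test singly (camera adjusted p = 0.00117; adjusted p = 0.715 with an estimated correlation). The same held for ribosomal proteins, with 30 of 40 members positive (camera adjusted p = 0.0258; adjusted p = 0.748 with an estimated correlation). Within cluster 8 alone the mean log2 changes of these lists were -0.029 and -0.265. Wild type replicates 6 to 10 and ob/ob replicate 2 consisted almost wholly of cluster 11 oocytes, at 89.5% to 100% and 92.6% of their cells, against 2.56% to 18.2% in the db/db libraries. Mitochondrial rows took 14.3% to 21.2% of the UMIs in wild type replicates 6, 7, 9 and 10, 5.52% in replicate 8 and 33.4% in ob/ob replicate 2, against 1.93% to 5.46% in db/db. Within cluster 8 alone the same comparison called 1378 genes, and leaving out any 1 db/db library left 66 to 80.

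**Figure D2:**
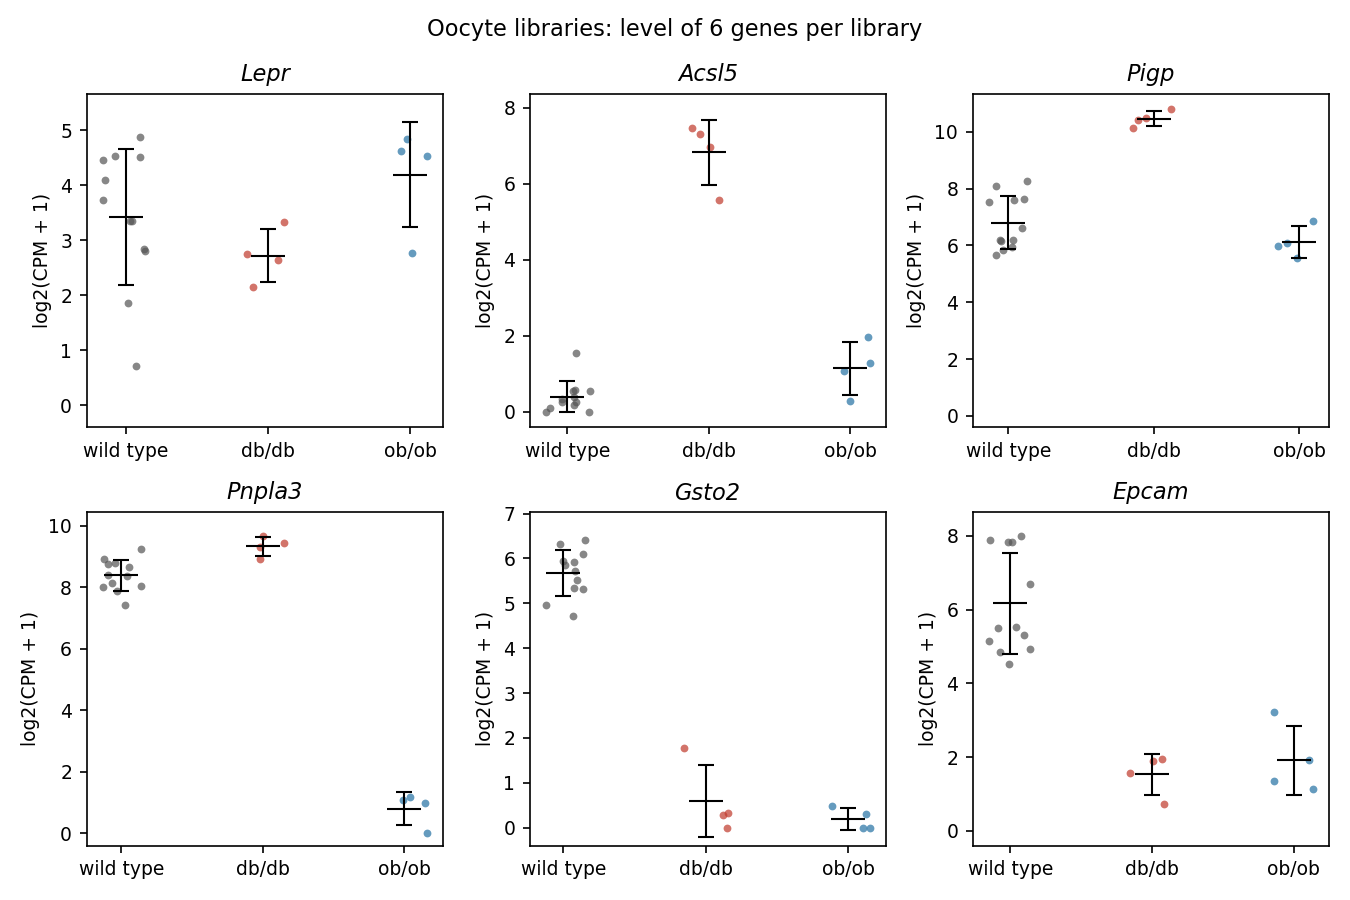
Levels of 6 genes in oocyte libraries as log2(CPM + 1), with 1 point per library, a bar for the mean and whiskers of 1 SD. Acsl5 averaged 126.3 CPM in the 4 db/db libraries and 0.380 in the 12 wild type libraries, and Pnpla3 0.831 in the 4 ob/ob libraries.

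In oocytes of ob/ob mice, 42 genes differed from wild type, of which 2 rose and 40 fell. Akr1cl, an aldo-keto reductase gene, rose from 41.9 ± 17.2 CPM (n = 12) to 122.9 ± 39.6 (n = 4). Pnpla3, a lipase gene of lipid droplets, fell from 351 ± 121.9 to 0.831 ± 0.567 CPM (adjusted p = 6.97e-08). Skint5 fell by 9.95 on the log2 scale and Manba fell by 5.60. Several genes that fell in db/db oocytes also fell here: AA465934 fell by 8.18, Gsto2 fell by 7.87, Slc27a2 fell by 7.65, Mtfr2 fell by 5.27 and Epcam fell by 5.03. Of 20 maternal effect genes, which oocytes store for the embryo, 18 were lower and none passed singly (camera adjusted p = 0.0362; adjusted p = 0.159 with an estimated correlation); Uhrf1 had a log2 change of -0.98, Kdm1b averaged 130 ± 17.3 against 221 ± 54.4 CPM and Zar1 929 ± 238 against 1421 ± 397. Oxidative phosphorylation genes lay higher, with 37 of 50 positive and none past the test (camera adjusted p = 0.00478; adjusted p = 0.776 with an estimated correlation). So did ribosomal proteins, with 34 of 40 positive and none past the test (camera adjusted p = 5.01e-04; adjusted p = 0.775 with an estimated correlation). The oocyte DNA methylation list had 10 of 12 members lower (camera adjusted p = 0.0219; adjusted p = 0.159 with an estimated correlation). Preantral and cumulus granulosa genes lay higher, with 7 of 8 positive, none past the test over all genes and 3 when adjusted over the list alone (camera adjusted p = 2.01e-04; adjusted p = 0.197 with an estimated correlation); Amhr2 averaged 3.17 ± 2.73 against 0.688 ± 0.571 CPM and Inhbb 8.57 ± 6.66 against 1.90 ± 2.36. The antral granulosa list was also higher, 1 of 10 when adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.159 with an estimated correlation), as were the granulosa markers (camera adjusted p = 5.82e-04; adjusted p = 0.153 with an estimated correlation) and theca markers (adjusted p = 0.145 with an estimated correlation). Whether the oocytes themselves held the RNA of these granulosa and theca genes was not tested. The share of calls that rose was 4.76% of 42, against 21.6% of 51 with DESeq2 size factors, 32.2% of 214 with the DESeq2 Wald test and 53.8% of 597 within cluster 8 alone. The balance of rises and falls thus depended on the cells, the scaling and the test. Without ob/ob replicate 1, 17 genes passed, and 21 without replicate 3 and 20 without replicate 4.

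Between the mutants, oocytes of db/db and ob/ob mice differed in 35 genes, 20 higher and 15 lower in db/db, whereas within cluster 8 alone 60 were higher and 92 lower, and the DESeq2 Wald test gave 46 and 57. Pnpla3 was higher by a log2 of 9.46 (adjusted p = 3.27e-08), and Manba stood at 138.7 ± 32.3 CPM in db/db and 0.460 ± 0.303 in ob/ob (n = 4 each). Skint5 was higher by a log2 of 8.49, Acsl5 by 6.61, H2-Aa by 6.04, Pigp by 4.30, Tceal8 by 3.84 and Trim15 by 2.41. The nuclear receptor gene Rora fell from 217 ± 40.8 CPM in ob/ob to 24.98 ± 7.37 in db/db, Aig1 from 1136 ± 563 to 37.9 ± 13.6, Inpp4a from 127.2 ± 49.2 to 7.17 ± 5.49, Sspn from 72.4 ± 41.7 to 1.39 ± 0.936 and mt-Nd3 from 884 ± 991 to 0.0486 ± 0.0709. Markers of theca were lower in db/db oocytes, with 8 of 8 negative (camera adjusted p = 4.28e-06; adjusted p = 0.0395 with an estimated correlation). So were luteal markers (camera adjusted p = 7.65e-05; adjusted p = 0.0598 with an estimated correlation).

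In granulosa-like cells, db/db differed from wild type in 701 genes, of which 265 rose and 436 fell, over 26 libraries each. The rises were led by Fam178b with a log2 of 3.89, the keratin gene Krt20 with 3.33, the pseudogene Rpl14-ps1 with 3.17, Clec1a with 2.94, Rgs13 with 2.38 and the glycoprotein hormone subunit gene Gpha2 with 2.33. mt-Nd3 fell from 525 ± 295 to 0.993 ± 1.19 CPM, Tmsb15b1 fell by 6.20 on the log2 scale, Rpl21 from 1625 ± 259 to 158 ± 66.9 CPM, Sft2d1 fell by 2.81, Rrad fell by 2.47, the secreted phospholipase gene Pla2g1b fell by 2.25 and the translation initiation factor gene Eif4a1 from 697 ± 125.1 to 155 ± 95.5 CPM. Rpl14-ps1 reads are uncertain, since its parent gene Rpl14 is nearly identical. Zp2 and Cd164l2, genes of oocytes, stood among the rises, at 50.4 ± 183 against 8.11 ± 13.5 CPM and 49.2 ± 166 against 7.19 ± 11.9, and in cluster 5 alone Zp2 was lower. The 13 oocyte markers measured did not pass as a list (mean log2 0.74, camera p = 0.104; p = 0.5675 with an estimated correlation), and their mean was -0.03 without 7 doubted libraries. Rgs13 had a log2 change of -0.43 in cluster 7 alone. The 3 surface epithelium markers measured fell (camera adjusted p = 0.00122; adjusted p = 0.0493 with an estimated correlation).

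Genes of the unfolded protein response, which handle protein folding in the endoplasmic reticulum, fell as a list in db/db granulosa-like cells, at a mean log2 of -0.212. In single clusters the mean was -0.305 in cluster 1, 0.065 in cluster 3, 0.183 in cluster 5 and -0.228 in cluster 7. Of 22 members 1 rose and 5 fell, and 1 and 6 when adjusted over the list alone (camera adjusted p = 8.50e-04; adjusted p = 0.281 with an estimated correlation). Pdia3 went from 1069 ± 209 to 712 ± 207 CPM, Pdia4 from 410 ± 99.8 to 283 ± 73.2, Manf from 871 ± 223 to 617 ± 181 and Dnajb9 from 193 ± 113.6 to 92.7 ± 53.2. Of 50 oxidative phosphorylation genes 13 fell and none rose, with 4 rising and 16 falling when adjusted over the list alone (camera adjusted p = 2.30e-05; adjusted p = 0.351 with an estimated correlation); Cox5b fell by 1.07 on the log2 scale, Cycs fell by 0.87, Ndufa4 fell by 0.70 and Atp5f1 fell by 0.44. In cluster 3 alone this list had a mean of 0.053. Of 20 oxidative stress defence genes 4 fell, and 1 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.281 with an estimated correlation); Prdx1 fell by 0.54, Sod2 fell by 0.59, Txnrd1 fell by 0.68 and Txn1 fell by 0.40. Of 40 ribosomal protein genes 18 fell and 1 rose, and 26 and 1 when adjusted over the list alone (camera adjusted p = 6.66e-14; adjusted p = 0.281 with an estimated correlation), Rps18 from 4145 ± 810 to 2420 ± 792 CPM. Meiotic maturation genes, many of them also used in mitosis, rose as a list, with 2 of 14 rising and 1 falling, the same when adjusted over the list alone (camera adjusted p = 0.0340; adjusted p = 0.484 with an estimated correlation); Plk1 rose by a log2 of 1.21 and Ccnb2 by 0.58, whereas Cnot7 fell by 0.73. Limma on the mean CPM of cells called 1069 genes, of which 70.7% were higher in db/db, against 37.8% of the 701, and in single clusters 15 to 43 genes passed.

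**Figure D3:**
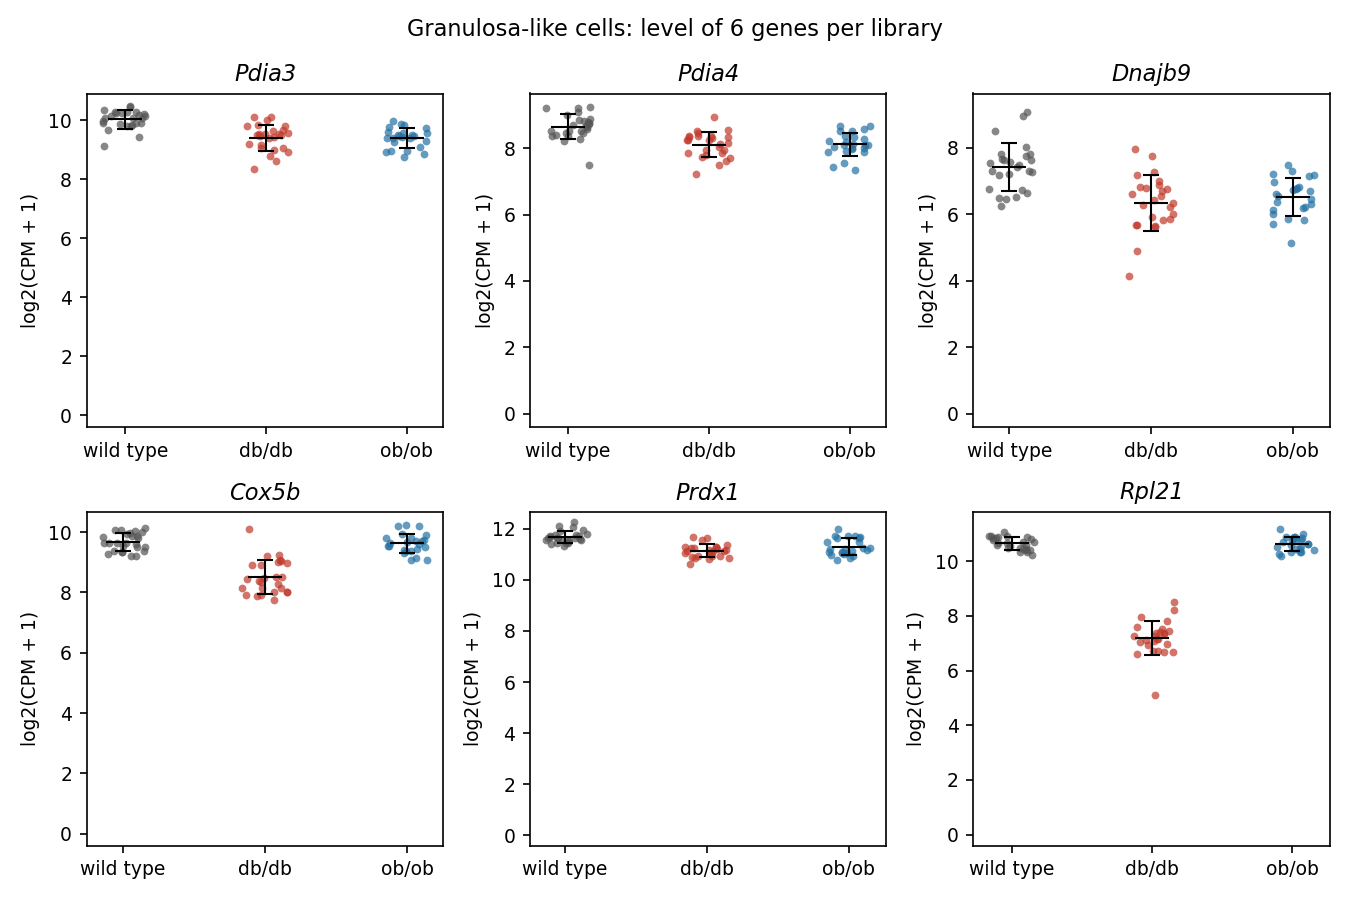
Levels of 6 genes in granulosa-like cells as log2(CPM + 1), with 1 point per library, a bar for the mean and whiskers of 1 SD. Rpl21 averaged 158 CPM in 26 db/db libraries and 1625 in 26 wild type libraries, and Dnajb9 averaged 92.7, 193 and, in 24 ob/ob libraries, 97.2 CPM.

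In granulosa-like cells of ob/ob mice (24 libraries against 26), 322 genes differed from wild type, of which 130 rose and 192 fell. Krt20 rose by a log2 of 3.58, Gpha2 by 2.33, Rasl10a by 1.95, Dnajb13 by 1.89 and Itih5, a hyaluronan-binding protein gene on the atresia list, by 1.66. The kinase gene Pim1 fell from 84.4 ± 88.3 to 3.72 ± 4.25 CPM (adjusted p = 1.42e-12). Rps15a-ps6, a pseudogene whose reads are uncertain, fell by 2.59, Mtus1 fell by 2.51, Rbfox1 fell by 2.39, the plasminogen activator gene Plat fell by 1.82, Hnrnpa1 fell by 1.81, Wdfy1 fell by 1.80 and Ablim1 fell by 1.62. The unfolded protein response list fell here too, with 1 of 22 rising and 4 falling, and 1 and 6 when adjusted over the list alone (camera adjusted p = 2.59e-04; adjusted p = 0.424 with an estimated correlation); Pdia3 fell by 0.62, Pdia4 fell by 0.53, Manf fell by 0.46 and Dnajb9 fell by 0.99. The mean log2 change of this list was -0.238, and 0.173 in cluster 5 alone. Cell cycle genes rose as a list, with 3 of 28 rising and none falling, and 3 when adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.556 with an estimated correlation): Plk1 rose by 1.26, Ccnb2 by 0.84 and Cenpa by 0.76. In cluster 3 alone the mean of that list was -0.022. Ribosomal proteins fell, 8 of 40, with 1 rising and 19 falling when adjusted over the list alone (camera adjusted p = 8.47e-08; adjusted p = 0.474 with an estimated correlation), but had a mean of 0.015 in cluster 5 alone. Limma on the mean CPM of cells called 604 genes, 68.5% of them higher in ob/ob, against 40.4% of the 322, and in single clusters 13 to 57 genes passed.

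Granulosa-like cells of the 2 mutants differed from each other in 96 genes, 41 higher and 55 lower in db/db. Pim1 stood at 111.4 ± 60.0 CPM in db/db and 3.72 ± 4.25 in ob/ob (n = 26 and 24), Fam178b at 80.7 ± 70.9 against 4.73 ± 8.01, Rbfox1 at 41.2 ± 47.7 against 3.71 ± 5.99 and Rpl14-ps1 at 272 ± 80.9 against 38.1 ± 13.4. mt-Nd3 fell to 0.993 ± 1.19 CPM in db/db from 344 ± 141.6 in ob/ob, Tmsb15b1 fell by 6.01 on the log2 scale, Rpl21 fell by 3.34, Rnaset2b fell by 2.57, the fatty acid transporter gene Slc27a1 fell by 2.55, Sft2d1 fell by 2.06 and Tmem205 fell by 1.93. Genes of growing oocytes and the zona pellucida were higher in db/db, 3 of 14, and 3 when adjusted over the list alone (camera adjusted p = 8.24e-04; adjusted p = 0.896 with an estimated correlation), with Zp3 higher by a log2 of 3.02 and Zp1 at 29.1 ± 94.9 against 3.56 ± 5.14 CPM. Maternal effect genes were higher as well, 2 of 19, and 4 when adjusted over the list alone (camera adjusted p = 0.00264; adjusted p = 0.740 with an estimated correlation), among them Khdc3 at 33.7 ± 93.1 against 3.95 ± 8.16. In cluster 3 alone the mean log2 changes of these lists were -0.175 and -0.141. The 13 oocyte markers measured moved with these lists, at a mean log2 of 1.62 (camera p = 1.91e-05; p = 0.141 with an estimated correlation), and of 1.02 without 7 doubted libraries. Oxidative phosphorylation genes were lower, 1 of 50, and 1 when adjusted over the list alone (camera adjusted p = 6.29e-05; adjusted p = 0.740 with an estimated correlation), and Cox5b fell by 1.04 on the log2 scale. Ribosomal proteins were lower, 2 of 40, and 4 when adjusted over the list alone (camera adjusted p = 0.00264; adjusted p = 0.896 with an estimated correlation), but higher in cluster 3 alone (camera adjusted p = 0.0402) and at a mean of 0.037 in cluster 7. Among libraries numbered under 110, 32 genes passed, and 78 among those from 110.

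Luteal-like cells, named only from the luteal marker list, differed between db/db and wild type in 97 genes (4 libraries each), of which 23 rose and 74 fell. Of the 10 db/db and ob/ob libraries of this class, 0 were also in the granulosa-like fit, so these cells came from separate libraries. Whether they were cells of a corpus luteum was not tested. The class was spread differently over its clusters. Cluster 10 held 204 of the 319 luteal-like cells of wild type somatic libraries. Cluster 4 held 259 of 371 in db/db and 240 of 422 in ob/ob. No luteal comparison was run within a single cluster, so a shift between clusters was not separated from these differences. Id1 and Id3, which restrain helix-loop-helix factors and respond to bone morphogenetic proteins, rose from 28.1 ± 9.82 to 124.2 ± 60.0 CPM and from 145.7 ± 62.2 to 525.9 ± 257. Fetub rose by a log2 of 1.80. The lipoprotein gene Apoe fell from 1104 ± 384 to 25.6 ± 19.4 CPM and the histocompatibility gene H2-Q10 from 362 ± 150 to 2.82 ± 0.741. mt-Nd3 fell by 7.86 on the log2 scale, Rnaset2b fell by 6.28, Sft2d1 fell by 3.86 and Rpl21 fell by 3.23. Ifi202b had 0 UMIs in db/db and in ob/ob, which allows up to 0.0459 and 0.0367 CPM over each group, against 38.1 ± 9.37 in wild type. Oxidative phosphorylation genes were lower as a list, with none of 50 past the test over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.0121; adjusted p = 0.775 with an estimated correlation); Cox7b had a log2 change of -0.72, and Ndufa9 averaged 169 ± 27.8 against 279 ± 12.9 CPM. Genes of growing oocytes were lower as a list, with none of 10 past the test (camera adjusted p = 0.0121; adjusted p = 0.554 with an estimated correlation). Leaving out db/db replicate 11 or 12 left 62 or 60 genes.

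In luteal-like cells of ob/ob mice (6 libraries against 4), 330 genes differed from wild type, of which 198 fell. The mix of clusters 4 and 10 differed here too, as given above, and was not separated from these differences. Socs3, a brake on cytokine and leptin signalling, rose from 16.5 ± 3.31 to 213 ± 167 CPM and the stress gene Gadd45g from 65.3 ± 51.1 to 409 ± 202. Interferon response and histocompatibility genes rose together, 3 of 17, and 7 when adjusted over the list alone (camera adjusted p = 2.17e-04; adjusted p = 0.0207 with an estimated correlation): Bst2 rose by a log2 of 1.30, Oasl2 by 2.44 and Ifitm3 by 1.04. Of the pathway lists that passed in the 12 comparisons, this 1 alone still passed with an estimated correlation. Apoe fell from 1104 ± 384 to 113.3 ± 86.2 CPM, the phosphate transporter gene Slc20a1 fell by 3.81, the carbonic anhydrase gene Car12 fell by 3.11 and the chemokine gene Cxcl14 fell by 2.27. Of 50 oxidative phosphorylation genes 8 fell, and 9 when adjusted over the list alone (camera adjusted p = 4.92e-04; adjusted p = 0.580 with an estimated correlation), among them Cox5a from 947 ± 179 to 544 ± 97.8 CPM, while Cox7b fell by 0.78 on the log2 scale. Cell cycle genes were lower, 1 of 28, and 1 when adjusted over the list alone (camera adjusted p = 0.00345; adjusted p = 0.580 with an estimated correlation), with Pcna from 96.5 ± 23.5 to 50.8 ± 13.6 CPM. Meiotic maturation genes were lower with none of 13 past the test (camera adjusted p = 0.0489; adjusted p = 0.580 with an estimated correlation). Ribosomal proteins were lower with 4 of 40, and 6 when adjusted over the list alone (camera adjusted p = 0.0497; adjusted p = 0.791 with an estimated correlation). Without wild type replicate 18 the comparison called 157 genes, and without replicate 20 it called 210.

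Luteal-like cells of db/db and ob/ob mice differed in 48 genes, 22 higher and 26 lower in db/db. The mix of clusters 4 and 10 was not separated from these differences either. Klrb1a stood at 52.1 ± 21.6 CPM in db/db and 3.60 ± 3.39 in ob/ob (n = 4 and 6), Pim1 at 54.01 ± 11.2 against 6.06 ± 8.67, Clec10a at 70.4 ± 30.2 against 9.37 ± 6.05 and Odc1, of polyamine synthesis, at 86.5 ± 22.3 against 17.3 ± 6.16. Bst2 was lower in db/db, at 117.5 ± 28.03 against 379 ± 91.8 CPM, as were H2-Q10, at 2.82 ± 0.741 against 475 ± 44.7, and A2ml1, at 0.788 ± 0.688 against 59.9 ± 50.2. Interferon response genes were lower in db/db as a list, 1 of 17, and 3 when adjusted over the list alone (camera adjusted p = 0.00998; adjusted p = 0.132 with an estimated correlation). Cell cycle genes were higher, with 23 of 28 positive and none past the test (camera adjusted p = 7.05e-06; adjusted p = 0.450 with an estimated correlation), with Ccnb1 at a log2 of 1.00. Cholesterol synthesis genes were higher, with 19 of 21 positive, none past the test and 1 when adjusted over the list alone (camera adjusted p = 6.74e-04; adjusted p = 0.651 with an estimated correlation), with Fdps at 2329 ± 520 against 1528 ± 227 CPM. Fatty acid oxidation genes were lower, with none of 18 past the test (camera adjusted p = 0.0257; adjusted p = 0.132 with an estimated correlation).

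**Figure D4:**
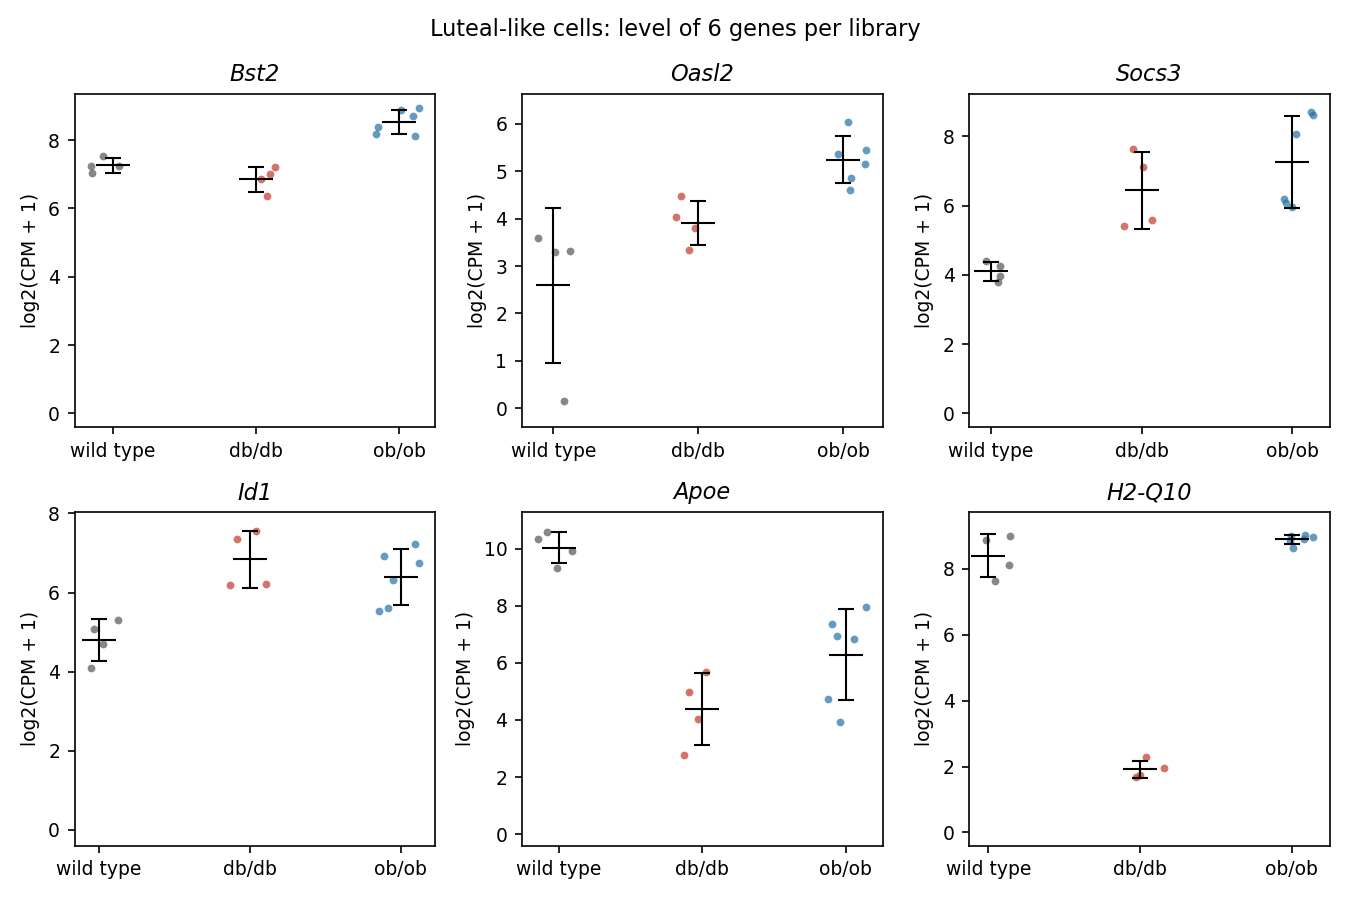
Levels of 6 genes in luteal-like cells as log2(CPM + 1), with 1 point per library, a bar for the mean and whiskers of 1 SD. Bst2 averaged 154 CPM in 4 wild type, 117.5 in 4 db/db and 379 in 6 ob/ob libraries, and H2-Q10 362, 2.82 and 475.

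Stroma-like cells differed between db/db and wild type in 34 genes (6 against 22 libraries), of which 20 rose and 14 fell. Some rises rested on db/db replicate 1, which held 6 such cells. Dlg3 stood there at 964.3 CPM, Ap3s2 at 807.0 and Tln2 at 801.9, against at most 7.68, 14.2 and 69.4 in the other db/db libraries. Rpl14-ps1 rose from 34.6 ± 25.8 to 355 ± 98.96 CPM. mt-Nd3 fell from 401 ± 157 to 1.08 ± 1.38 CPM, Cnrip1 from 83.01 ± 54.4 to 0.689 ± 1.11, Rnaset2b fell by 6.62 on the log2 scale, the extracellular superoxide dismutase gene Sod3 fell by 5.65 and the receptor gene Ryk fell by 6.80. Extracellular matrix genes were lower as a list, none of 25 past the test and 1 when adjusted over the list alone (camera adjusted p = 5.34e-04; adjusted p = 0.102 with an estimated correlation); Timp3 averaged 43.2 ± 41.9 against 168 ± 96.6 CPM and Col1a1 417 ± 148.6 against 755 ± 275. Maternal effect genes were higher, 17 of 17 positive (camera adjusted p = 8.04e-06; adjusted p = 0.102 with an estimated correlation), as were growing oocyte genes, 9 of 11 positive (camera adjusted p = 1.25e-06; adjusted p = 0.309 with an estimated correlation), beside oocyte markers (camera adjusted p = 6.83e-09; adjusted p = 0.120 with an estimated correlation). Single libraries stood out here. Ooep was at 148.8 CPM in db/db replicate 9, a doubted library with 4 oocyte-like cells, and at most 50.2 in the other db/db libraries. Omt2b was at 111.9 CPM in replicate 8 and at most 37.6 in the others. Oocyte RNA in these libraries was not separated from a change of the stroma-like cells. The median log2 change over all genes was -0.197, and -0.001 with DESeq2 size factors. With DESeq2 size factors 150 genes passed, 85.3% of them higher in db/db against 58.8%, and with at least 10 cells per library 63 rose and 46 fell.

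In ob/ob stroma-like cells (13 libraries against 22), 46 genes rose and 57 fell. Pim1 fell from 164 ± 79.7 to 4.37 ± 5.95 CPM (adjusted p = 3.61e-08), the heme oxygenase gene Hmox1 fell by 2.57, Wdfy1 fell by 2.76 and the protease gene Adamts1 fell by 1.22. Extracellular matrix genes were lower as a list, 1 of 25, and 2 when adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.136 with an estimated correlation). Granulosa and surface epithelium markers were higher in these cells (adjusted p = 0.00716 for both with an estimated correlation), and antral granulosa genes rose beside them, 1 of 9, and 2 when adjusted over the list alone (camera adjusted p = 6.23e-04; adjusted p = 0.136 with an estimated correlation), Hsd17b1 from 21.5 ± 18.3 to 86.3 ± 93.3 CPM. Steroid hormone synthesis genes were higher, 1 of 13, and 1 when adjusted over the list alone (camera adjusted p = 0.0152; adjusted p = 0.344 with an estimated correlation). So was the preantral granulosa list, none of 10 and 1 when adjusted over the list alone (camera adjusted p = 0.0216; adjusted p = 0.344 with an estimated correlation). With at least 10 cells per library the mean log2 changes of the antral, steroid and preantral lists were -0.442, -0.035 and -0.387. Stroma markers were lower (adjusted p = 0.0275 with an estimated correlation). The median log2 change over all genes was 0.069, and 0.213 with DESeq2 size factors. With at least 10 cells per library 4 genes passed, and with DESeq2 size factors 164, 64.6% of them higher against 44.7%.

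Stroma-like cells of db/db and ob/ob mice differed in 67 genes, 39 higher and 28 lower in db/db, and 8 of 100 splits of these libraries gave at least as many. Pim1 stood at 167 ± 163 CPM in db/db and 4.37 ± 5.95 in ob/ob (n = 6 and 13), Rnaset2b at 0.394 ± 0.645 against 137.1 ± 79.0, Cnrip1 at 0.689 ± 1.11 against 89.9 ± 120.5 and mt-Nd3 at 1.08 ± 1.38 against 276 ± 149.3. Antral granulosa genes were lower in db/db, 8 of 9 negative and 1 past when adjusted over the list alone (camera adjusted p = 0.0213; adjusted p = 0.345 with an estimated correlation). Growing oocyte genes were higher, 10 of 11 positive (camera adjusted p = 2.72e-06; adjusted p = 0.345 with an estimated correlation), as were maternal effect genes, 10 of 17 positive (camera adjusted p = 0.00569; adjusted p = 0.345 with an estimated correlation), with none past the test. Oocyte RNA in single db/db libraries, as given above, was not separated from this either. The median log2 change over all genes was -0.256. With at least 10 cells per library 9 genes passed.

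The effects of both mutants against the same wild type libraries were compared across genes, which are not independent replicates. Both mutants also share a strain label and a range of library numbers that wild type lacks. Neither the simulation nor the split below removes this, so similarity due to strain or library run cannot be told from similarity due to the mutations. In granulosa-like cells 81 genes rose and 1.3e+02 fell in both mutants, and 2 moved in opposite directions. The Pearson correlation of log2 changes was 0.611 in granulosa-like cells, where unchanged groups simulated against the same wild type libraries gave 0.487, and 0.306 with the wild type libraries split between the comparisons (mean of 10 draws, SD 0.0111). With that split a mean of 16.7 genes rose and 51.7 fell in both mutants. Each comparison then had fewer wild type libraries and called a mean of 338.7 genes in db/db and 146.1 in ob/ob. Independent lists of those sizes would share 0.541 risen and 2.30 fallen genes. The split takes away the shared libraries, so its values are not those of unchanged groups. The covariance was 0.269 against 0.0984 simulated. In oocytes the correlation was 0.605 against 0.235 simulated, with a covariance of 0.528 against 0.119. Splitting the oocyte wild type libraries gave a mean of 0.347 with an SD of 0.245 and a lowest value of -0.155, so the sign depended on the draw. In luteal-like cells the correlation was 0.689 against 0.560 simulated, and 0.217 with the wild type libraries split, with a covariance of 1.20 against 0.621 simulated. In stroma-like cells it was 0.198 against 0.246 simulated, and 0.0957 with the split, with a covariance of 0.348 against 0.203 simulated.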

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

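The congenic test, the final definition of a neighbour, the abundant transcript thresholds and the use of both contrasts for the oocyte and cluster tests, and of an interval for the spike-in test, were chosen after some results had been seen.

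Between db/db and ob/ob granulosa-like cells, 50 genes differed by over 4-fold, 33 higher and 17 lower, such as Pim1, Rpl21 and Rnaset2b. These genes lay beside each other more often than random sets of tested genes did: 12.5% of the 48 placed had another gene of over 4-fold as a neighbour, against a 95th percentile of 4.17% (16.3% of 92 against 5.43% for all called genes), which is consistent with variants linked on a chromosome. In luteal-like cells 26 of the 32 genes tested kept their sign (81.2%, exact 95% interval 63.6% to 92.8%), and in oocytes 86.4% did, whereas the 83.3% in stroma-like cells came from libraries that also gave the granulosa-like cells, which leaves a congenic or strain variant open. Reads shared with paralogs stay open too, since the Rpl21 family (log2 -3.29) had 1 row, and the Rpl14 (-0.02) and Rps15a (-0.38) family sums are too large for Rpl14-ps1 (2.91) and Rps15a-ps6 (2.61) to move them much. The parent rows were lower in db/db, Rpl14 at a log2 of -0.22 and Rps15a at -0.49. For Rpl14, reads moved between rows would also give this gap. It lay within the spread, at 1622 CPM without TMM scaling (SD 437.1) in db/db and 1890 (SD 594.6) in ob/ob. The Rps15a gap did too, at 1356 CPM (SD 710.8) in db/db and 1903 (SD 281.7) in ob/ob. Moved reads could give at most part of it, since Rps15a-ps6 stood at 123.2 CPM in db/db, 20.2 in ob/ob and 116.8 in wild type. A difference of the genotypes themselves was not separated from these explanations.

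The 13 oocyte markers measured had a mean log2 change of 0.74 in db/db granulosa-like cells against wild type (camera p = 0.104) and 1.62 against ob/ob, with db/db replicate 23 at 9909 CPM in 11 such cells, wild type replicate 26 at 2708 and ob/ob replicate 21 at 1716. Of 82 abundant oocyte transcripts outside the lists, the median log2 change was 0.85 against wild type and 1.28 against ob/ob, which is consistent with oocyte RNA in these libraries. Picking genes low in wild type granulosa-like cells favours a rise in the former contrast. Without the 7 doubted libraries the mean changes were -0.03 (camera p = 0.169) and 1.02 (2.75e-05, and 0.125 with an estimated correlation), but wild type replicates 26 and 31, at 2708 and 1601 CPM, stayed in and lay above every db/db library kept. Replicates 5 to 8 and 10 of db/db, at 433 to 1026 CPM, stood above the other db/db libraries kept, so that a difference of some libraries and a general one of db/db cells both stay open.

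The unfolded protein response list was lower in both mutants against wild type by camera at the preset correlation, but passed in neither with an estimated correlation. The spike-in share of somatic libraries had medians of 38.3% in wild type, 17.3% in db/db and 19.8% in ob/ob. Among 50 mutant libraries the list level had a Pearson r of 0.233 with it (95% interval -0.0485 to 0.480, permutation p = 0.103, adjusted 0.284 over 4 relations, 0.212 without the 2 farthest libraries, Spearman rho 0.195, 0.33 in ob/ob and 0.314 in wild type), which leaves spike-in share open. Within clusters the mean log2 change of the list lay above -0.1 in 2 of the 3 clusters tested for db/db (0.065 in cluster 3 and 0.183 in cluster 5) and in 1 for ob/ob (0.173 in cluster 5), whereas it was -0.228 and -0.270 in cluster 7 and -0.305 and -0.378 in the largest cluster, so a shift between clusters stays open. Strain and library run cannot be told apart from genotype, since 0 wild type libraries were numbered within the range of the mutants.

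Other splits of the same libraries gave fewer genes than the real split in most comparisons, each real split being the 1 as large. That argues against a random grouping of libraries there. The splits exchanged libraries and the labels name no animal, so a chance difference between animals or runs of libraries was not excluded. Granulosa-like cells had 701, 322 and 96 genes against at most 30, 4 and 59 in the other splits. Luteal-like cells had 97, 330 and 48 against at most 0, 5 and 24. Stroma-like cells had 34 in db/db against at most 8, and 46 risen and 57 fallen in ob/ob against at most 14 in all. Oocytes had 35 against at most 0 between the mutants. For oocytes against wild type 2 of 100 splits were as large as the real ones, which called 35 risen and 110 fallen genes in db/db and 42 in ob/ob. The other called 8222 and 7977 genes, which points to a structure of the libraries, of which the kind was not tested. For stroma-like cells of db/db against ob/ob 8 of 100 splits gave at least the 67 genes, at most 1.5e+02, so chance cannot be excluded.

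In 24 of 176 groups of 4 to 10 libraries tested, 1 library lay far from the others, where a flat rate of 1 in 20 gives 8.8. Over all named genes 1 did in 61 of 403, where that rate gives 20.1. The rule was also applied to values near 0, where a trace in 1 library can set a flag. Skint5 and Ryk below were flagged against 0 CPM in the other libraries of their groups. The excess over that rate therefore does not by itself show aberrant libraries. In ob/ob oocytes replicate 2 stood apart for H2-Aa at 0 CPM, mt-Nd3 at 2361, Mtfr2 at 20.0, Sspn at 134.8 and Rplp1 at 171.9, replicate 1 for Skint5 at 0.0434 CPM and a UMI total of 21249964, and replicate 3 for Inhbb at 18.5. In db/db oocytes replicate 1 stood apart for Gsto2 at 2.44 CPM, Ndufb8 at 462.7 and a spike-in share of 1.61%, and replicate 4 for Tceal8 at 77.1. In db/db luteal-like cells replicate 13 stood apart for Fetub at 72.3 CPM, Cox7b at 583.7 and Fdps at 3109, and replicate 12 for Rpl21 at 90.1. In ob/ob replicate 31 did for Rpl21 at 760.1 and replicate 10 for Pim1 at 23.2. In db/db stroma-like cells replicate 2 stood apart for Rpl14-ps1 at 545.9 CPM and Hmox1 at 288.8, replicate 1 for Wdfy1 at 284.2 and Adamts1 at 791.8, replicate 9 for Timp3 at 124.6 and replicate 27 for Ryk at 0.854.

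In the db/db mixed libraries, 93 of the 96 cells of replicate 1 were luteal-like and 91 of the 92 cells of replicate 2 lay in cluster 19, led by macrophage markers, of which no library of another group held over 2. In the library with no genotype 47 of 92 cells lay in cluster 24, of which no other library held over 10.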

How the results depend on the processing

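Other clustering resolutions, mitochondrial rows left out, single clusters other than the largest, clusters 8 and 15, added unnamed clusters, library number subsets, doubted libraries left out and luteal libraries left out in turn were chosen after seeing the data. Of 159 alternative values of main results 50 moved beyond 1.5 times or 1 SD. Of 4379 for named genes and lists 3743 kept direction and side of the threshold, 575 lost the threshold, 34 passed it anew and 27 changed sign. Where no cause is named the cause was not tested. No paired analysis was possible because replicate numbers were given in accession order. The DESeq2 Wald test called 577, 214 and 1.0e+02 (46 higher and 57 lower) genes in oocytes for db/db and ob/ob against wild type and db/db against ob/ob. It called 616 in granulosa-like cells for ob/ob against wild type. The largest cluster gave 1378, 597 and 1.5e+02 (60 higher and 92 lower) in oocytes and 36, 13 and 16 in granulosa-like cells, and clusters 8 and 15 gave 1432, 661 and 224 in oocytes. In granulosa-like cells no low count filter gave 3174, 2611 and 1899, and limma on the mean CPM of cells 1069 and 604 against wild type. Added unnamed clusters gave 603 for ob/ob against wild type. Cluster 3 gave 15, 57 and 14, cluster 5 gave 37, 30 and 49, cluster 7 gave 43, 38 and 40, and libraries numbered under 110 gave 32 between the mutants. Limma moved the median log2 change over all genes to 0.228 and 0.149 there. Single clusters and subsets hold fewer cells or libraries. Leaving out 1 library, tried only for genotypes with 2 to 5 libraries, gave 66 to 80, 17 to 36 and 25 to 38 genes in oocytes and 60 to 1.1e+02, 157 to 317 and 38 to 42 in luteal-like cells. In stroma-like cells DESeq2 size factors gave 150 and 164 against wild type, and at least 10 cells per library 1.1e+02 (63 higher and 46 lower), 4 and 9. Of the pathway lists 1 passed with an estimated correlation. With wild type libraries split, the correlation of both mutants' effects was 0.347 in oocytes (SD 0.245, lowest -0.155), 0.306 in granulosa-like, 0.217 in luteal-like and 0.0957 in stroma-like cells. List means changed sign for oxidative phosphorylation (-0.029) and ribosomal proteins (-0.265) in the largest cluster, and for the latter (-0.251) in clusters 8 and 15, for db/db against wild type in oocytes. In granulosa-like cells they did for oxidative phosphorylation (0.053) and unfolded protein response (0.065) in cluster 3 and the latter (0.183) in cluster 5 for db/db against wild type. For ob/ob they did for cell cycle (-0.022) in cluster 3 and unfolded protein response (0.173) and ribosomal proteins (0.015) in cluster 5. Between the mutants they did for growing oocyte (-0.175) and maternal effect (-0.141) genes in cluster 3 and ribosomal proteins (0.037) in cluster 7. With at least 10 cells per library in stroma-like cells they did for steroid hormone synthesis (-0.035), antral (-0.442) and preantral (-0.387) granulosa genes in ob/ob against wild type. Signs also changed for Cd164l2 (-1.43) and the ribosomal list (0.145) in cluster 3 and Ooep (-0.70) in cluster 5 between the mutants. They changed for Zp2 (-1.22) in cluster 5 and Rgs13 (-0.43) in cluster 7 for db/db against wild type. With at least 10 cells per library in stroma-like cells they changed for Dlg3 (-0.86), Tln2 (-0.66) and Ap3s2 (-2.24) in db/db and Cep162 (-3.00), Tmem44 (-1.83), Cerk (-2.57) and Tbc1d2b (-1.07) in ob/ob against wild type. Adding the mixed libraries says nothing, as they held too few oocyte-like or granulosa-like cells, and the stricter cell filter moved no class share beyond 1 SD.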

Other observations

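The gene tables of cluster 8 and the chromosome count were chosen after results had been seen. Within oocyte cluster 8 (7 wild type, 4 db/db and 3 ob/ob libraries) 594 genes rose and 784 fell in db/db against wild type, and 321 rose and 276 fell in ob/ob. Lepr fell in db/db to 7.70 ± 4.84 CPM from 28.7 ± 11 in wild type (edgeR adjusted p = 0.00171) and stood at 33.9 ± 7.32 in ob/ob (adjusted p = 0.00467 for db/db against ob/ob). Inha, the inhibin alpha gene, rose from 24.7 ± 12.8 CPM to 145.2 ± 105.4 in db/db and 115.1 ± 31.1 in ob/ob, and Cmtm8 rose by a log2 of 2.44 and 2.08. The maternal effect genes Khdc3, Kdm1b, Uhrf1 and Nlrp5 fell in ob/ob, by a log2 of -1.24, -1.01, -0.95 and -0.86, 4 of 20 listed members, and 4 when adjusted over the list alone (camera adjusted p = 0.00532; adjusted p = 0.108 with an estimated correlation).

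Antral granulosa genes rose in ob/ob cluster 8 oocytes, 4 of 8, and 6 when adjusted over the list alone (camera adjusted p = 4.39e-04; adjusted p = 0.108 with an estimated correlation), with Hsd17b1 at 8.73 ± 5.68 against 1.17 ± 0.868 CPM, and granulosa markers were higher too (camera adjusted p = 5.20e-06; adjusted p = 0.0649 with an estimated correlation). Whether the oocytes themselves held the RNA of these granulosa genes, and of Inha above, was not tested. Spesp1, Bfsp1, Defa29 and Gsto2 had 0 UMIs in both mutants, which allows up to 0.453 CPM over the db/db and 0.269 over the ob/ob libraries, against 41.5 ± 9.69, 66.9 ± 33.8, 80.1 ± 34.9 and 60.6 ± 8.77 CPM in wild type. The oocyte markers fell in both mutants (adjusted p = 0.0315 and 0.0187 with an estimated correlation).

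Of the 92 placed genes called between db/db and ob/ob granulosa-like cells, 17 lay on chromosome 17 (GRCm38 annotation), where 4.45 of the 496 genes tested there would be expected (hypergeometric p = 1.59e-06, adjusted over chromosomes 3.19e-05). They included Pim1, Rnaset2b, Sft2d1, Glo1 and Rps18. Chromosomes 4 and 6 held 5 and 6 called genes, where 5.78 and 4.68 would be expected. By the same hypergeometric test the lowest adjusted p of any other chromosome was 0.907, on chromosome 9.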
